A study of Acropora tenuis with 242 samples.

How the data were processed

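RNA was extracted from larval and juvenile tissue of Acropora tenuis with the RNAqueous kit (Ambion) and sequenced as tag-based libraries, per the labels' protocols. The authors deposited 1 table of raw read counts per life stage, with a gene model in each line and a library in each column, 25142 gene models for larvae and 25349 for juveniles. Bowtie2 (version 2.2.9) is named in the submitters' processing notes. The column names end in trim, sam and counts, and those of juveniles also carry the word host, per the file headers. The counting step, the reference and any removal of duplicate reads or of algal sequences are not given in the sources used here, so the counts were taken as deposited. They are whole numbers with unequal totals, and all lines name a gene model. Whether the counting split reads between near-identical copies is not stated, so a value of a single model can hold reads of its copies. The most abundant model took on average 1.07% of the counts in larvae and 2.73% in juveniles.

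Each column was assigned to a sample through the title in its name, and the group (life stage, cross, temperature and, in juveniles, symbiont treatment) was taken from the labels. All 242 libraries were used. Replicate libraries of a group were compared by a chi-square test of their counts, and no pair of the 96 larval and 134 juvenile pairs agreed within sampling noise (chi-square per degree of freedom 1.06 to 4.90 and 2.45 to 11.4), so none was treated as a repeat of another library. The test covers counting error alone, so it shows neither that libraries of a group are separate samples nor that they came from separate cultures. Depth was the total count per library. Library size factors were estimated by the trimmed mean of M-values (TMM) and levels are given as CPM (counts scaled to a common library total) on those sizes. Log2 CPM values used a prior count of 2.

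Gene models were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, filterByExpr for low counts), and a model was called at a Benjamini-Hochberg false discovery rate of 0.05. Larval heat, time, Hot against Pre and population differences used counts summed over the libraries of a cross and treatment, which gave 32 profiles, with cross and treatment as terms. The difference in heat response between larval crosses used the 60 Hot and Ambient libraries of the 10 crosses with both. Symbiont treatments were compared among the 119 Ambient juvenile libraries with cross and symbiont as terms. Juvenile heat was tested in 69 libraries with a term for each combination of cross and symbiont treatment, and with a temperature effect per symbiont treatment for the difference between treatments. Population and reciprocal tests used the 58 Ambient juvenile libraries of the within-population crosses and the 25 of CUxDR and DRxCU.

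The gene models named were chosen by a rule set before the data were examined: for each comparison the 2 rising and 2 falling models with the largest fold change among those called, with a mean log2 CPM of at least 3, and with the same direction in every larval cross or in at least 80% of juvenile crosses or combinations. The rule foresaw 5 per direction and fixed lists (chaperones, antioxidants, immunity, apoptosis, fluorescent proteins, calcification, nutrient transport, ribosome, electron transport, cell cycle, cilia, lipid metabolism and algal genes) if names could be attached. The files do not pair identifiers with names, so these lists could not be tested and are not used here. Fold changes are fitted values, except in symbiont contrasts where the lower group held under 25 counts, where a rate ratio of summed counts with its exact 95% interval is given.

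The parental scale took gene models called between the 2 within-population crosses at Pre (larvae) or C1 (juveniles) and fitted, in the other treatments, the slope of the between-population cross on the distance between them. It needed at least 20 models. The correlation and covariance of log2 fold changes between contrasts that share control libraries were set beside 20 simulations without effects on the same controls. Overlap counts were set beside independent lists alone. Correlations across crosses used 1e+05 permutations. A mean over the 22 models low in SED was compared between temperatures by permutation within combinations, exact for SS (1000 arrangements) and D1 (2500 arrangements).

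Column names carry an index number, and juvenile libraries fell into an early (42 to 162) and a late block (273 to 297), which were examined only after the data were seen. The larval libraries lay between them (177 to 272). Thinning drew each juvenile library down to 158481 counts once, and larval libraries to 536230. The alternatives were DESeq2 1.42.0 as the test, its size factors in edgeR, no low-count filter, libraries in place of sums, a replicate block, leaving out each replicate number or each cross, other covariates, other thresholds, and, added after the data were seen, the index blocks and the index number as a covariate.

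The fits named in this paragraph, and not the other comparisons or checks, were tested on simulated data. Counts were drawn from the real means and library sizes, with 200 models changed by known folds. For larval heat 47.8%, 77.6% and 98.5% of models changed 1.5-, 2- and 4-fold were called among 13830 models tested, with 5 unchanged models called. The larval cross by temperature test, with the change put in SBxSB alone, called 2.99%, 28.4% and 66.7% among 10658, so small differences of a single cross are mostly missed. SED against C1 called 74.6%, 100% and 95.5% among 8707, juvenile heat 64.2%, 92.5% and 95.5% among 9047, and the reciprocal test 31.3%, 68.7% and 97% among 7532. On the parental scale, tested with made-up means in place of the real ones, true positions of -0.5, 0 and 0.5 were recovered as -0.496, -0.00364 and 0.491.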

Results

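Gene expression was measured in Acropora tenuis, a reef-building coral, by tag-based RNA sequencing, in which a short fragment of each transcript is sequenced and counted per gene model. The animals were crosses within and between 5 populations of the Great Barrier Reef, which the labels call BK, CU, DR, LS and SB, and a cross is named here as the labels name it (CUxBK). The larval set held 96 libraries from 11 crosses. Of these, 33 were taken before the temperature exposure (Pre), 33 after it at control temperature (Ambient) and 30 after it in the heated treatment (Hot), which LSxSB lacked. The juvenile set held 146 libraries from 10 crosses, raised under 4 symbiont uptake treatments labelled C1, D1, SED and SS, whose codes are not spelled out in the labels. At Ambient there were 29 C1, 32 D1, 28 SED and 30 SS juvenile libraries. At Hot there were 6 D1, 15 SED and 6 SS libraries and 0 of C1. Total counts ran from 79712 to 1102351 per larval library with a median of 871515.5, and the shallowest, LSxCU Pre replicate 2, was the only larval library under 536230. Juvenile libraries held 158481 to 962906 counts with a median of 369969.5. At these depths a gene at 10 CPM was represented by few counts in a juvenile library, so low values there are imprecise. Nothing in the labels says whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries or crosses, part of which can be technical. Gene models carry identifiers such as Amillepora13086-RA that the files do not pair with gene names, so 2 rising and 2 falling models are named per comparison.

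The first comparison asked how larvae responded to heat. Amillepora13086-RA rose from 5.70 ± 8.47 CPM at Ambient to 262.5 ± 111 CPM at Hot (SD over 10 crosses), a 60.2-fold change. Amillepora13087-RA was the other leading gene that rose, from 210.3 ± 260.9 to 2999 ± 486 CPM, or 23.8-fold. Amillepora12537-RA fell from 12.8 ± 5.22 to 0.974 ± 1.24 CPM, and Amillepora04321-RA fell from 636.8 ± 228.1 to 59.05 ± 46.77 CPM, 12.4-fold. Single crosses raise the Ambient means of the 2 rising models, which are 3.345 ± 4.277 CPM for Amillepora13086-RA without DRxSB and 133.9 ± 104.7 CPM for Amillepora13087-RA without CUxBK (n = 9). All 4 moved in the stated direction in 10 of 10 crosses, which the rule that chose them required. The log2 fold change of Amillepora13086-RA was 5.91 (SE 0.48, adjusted p = 1.23e-09, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and that of Amillepora04321-RA was -3.63 (SE 0.37, adjusted p = 2.91e-08). Across the transcriptome 5915 of 14413 tested gene models differed, 3066 higher and 2849 lower at Hot, and 1351 of them differed at least 2-fold. Larvae from the same cross and treatment were summed to 1 profile for this test, so that each cross counted as 1 replicate.

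**Figure D1:**
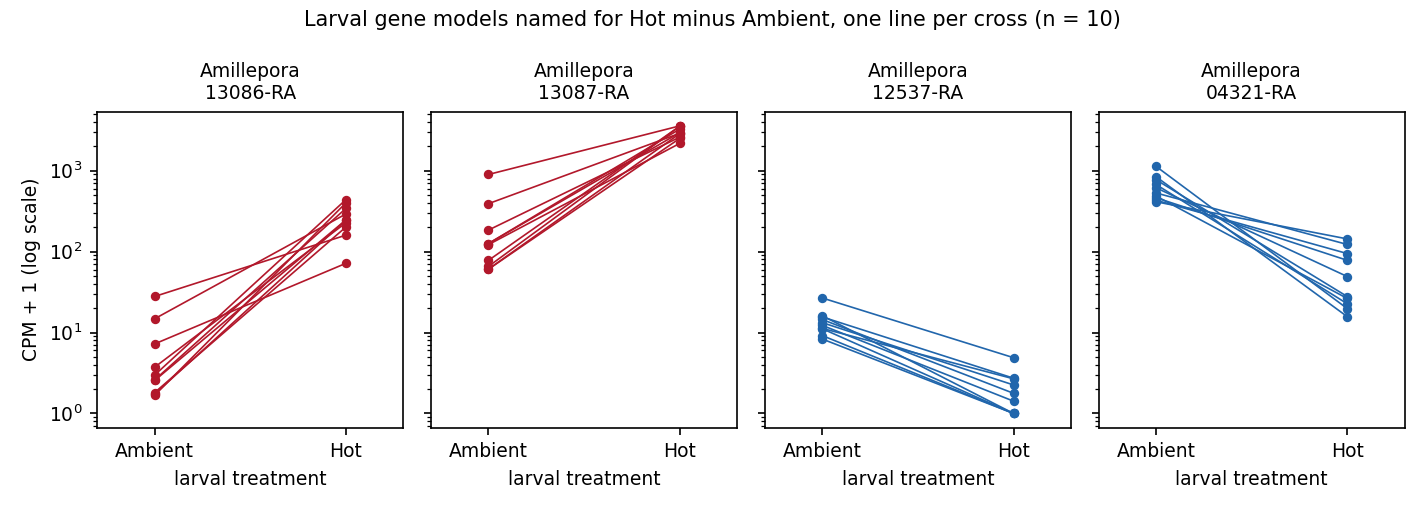
CPM + 1 on a log scale at Ambient and Hot for the 4 gene models named in the larval heat comparison, with a line joining the 2 summed profiles of each of the 10 crosses. Amillepora13086-RA and Amillepora13087-RA rose and Amillepora12537-RA and Amillepora04321-RA fell in every cross, which the rule that chose them required.

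Between the Pre and the Ambient sampling, at control temperature, the largest changes were decreases. Amillepora12585-RA fell from 962 ± 587.6 CPM before the exposure to 83.9 ± 38.5 CPM after it (SD, n = 11 crosses), an 11.5-fold drop, and Amillepora06876-RA fell from 41.2 ± 59.5 to 3.02 ± 4.91 CPM (25.16 ± 28.32 CPM at Pre without LSxSB and 1.656 ± 1.995 CPM at Ambient without DRxSB, the highest crosses). Amillepora01048-RA rose 3.74-fold, from 6.47 ± 4.26 to 23.6 ± 7.08 CPM, and Amillepora22000-RA rose 3.33-fold, from 11.6 ± 6.08 to 38.9 ± 17.9 CPM. All 4 moved in the same direction in 11 of 11 crosses, again a condition of their choice. Of 14413 gene models, 424 were higher and 1075 lower at Ambient than at Pre (edgeR, false discovery rate 0.05). With libraries in place of summed profiles as the replicates, 3680 models passed, 1872 higher and 1808 lower, so the excess of decreases among calls depends on that choice. Hot against Pre gave 5714 models, 2798 higher and 2916 lower.

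The size of the larval heat response differed between crosses. In each cross the log2 fold changes were set against the mean effect of the other crosses over the gene models called in those, so that a slope of 1 is the response of the others. The slope was lowest in CUxBK, at 0.589 ± 0.046 (SD, n = 3 pairs of Hot and Ambient libraries), where 70.97% of these models moved in the direction of the other crosses. Libraries were paired by replicate number, which is arbitrary, so the SD is no measure of spread between cultures. The next lowest was LSxCU at 0.802 ± 0.0087, and the highest was SBxSB at 1.19 ± 0.043. A test of the difference itself, cross by temperature, called 3418 of 11241 gene models (edgeR quasi-likelihood F-test over 10 crosses). Within single crosses 2307 (LSxCU) to 3838 (SBxSB) models differed between Hot and Ambient. A set of 410 models was called in 1 direction in all 10 crosses, 187 of them down and the rest up, and 722 were called up in at least 1 cross and down in at least 1 other. Across gene models the correlation of log2 fold changes between 2 crosses was 0.322 to 0.685 with a median of 0.565, and gene models are not independent replicates. All libraries of a cross and treatment share 1 title number, so the spread in this test is that between libraries that cannot be assigned to separate cultures. Crosses with deeper libraries had the smaller slopes, with Spearman's rho = -0.709 (permutation p = 0.0266) and Pearson's r = -0.71 (permutation p = 0.0224) over 10 crosses, and r = -0.369 without the 2 crosses farthest from the median depth, so this relation rests on those 2.

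**Figure D2:**
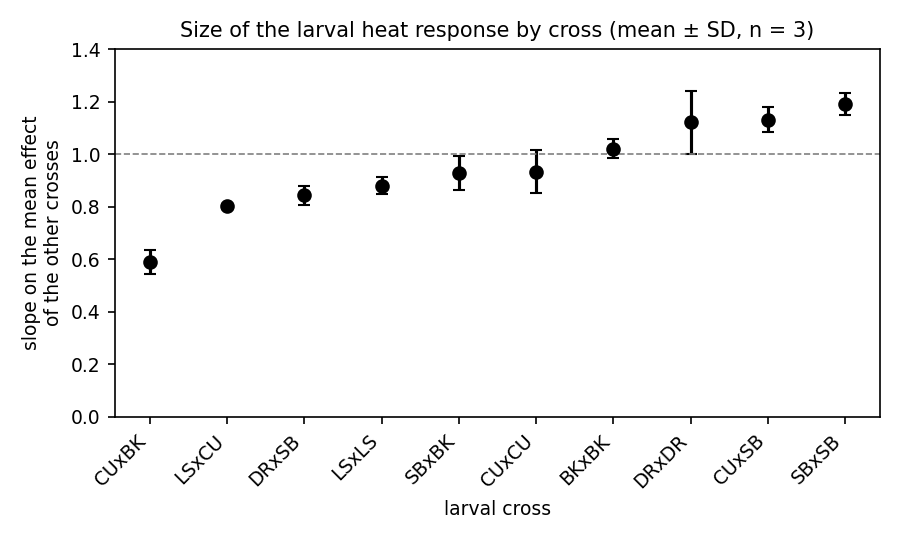
Slope of each larval cross's Hot minus Ambient log2 fold changes on the mean effect of the other crosses (no unit), as mean ± SD over 3 pairs of Hot and Ambient libraries per cross, paired by replicate number, with a dashed line at 1. CUxBK lies lowest at 0.589 and SBxSB highest at 1.19.

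Heat-induced gene models were next set against their level before exposure, cross by cross. Over 10 crosses the mean Pre level of the models that rose with heat and the size of their rise gave Spearman's rho = -0.564 (permutation p = 0.0946, Benjamini-Hochberg adjusted p = 0.189 over the 2 relations tested) and Pearson's r = -0.57 (permutation p = 0.0824, adjusted p = 0.105). Without the 2 crosses farthest from the median Pre level, r was -0.559. For the models that fell, rho was -0.236 (permutation p = 0.513, adjusted p = 0.513) and r was -0.543 (permutation p = 0.105, adjusted p = 0.105), turning to 0.364 without the 2 farthest crosses. Neither relation passed the threshold.

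The 5 within-population crosses also differed from each other on average over treatments: 1070 of 13208 gene models were called among them in larvae, 4991 with libraries as the replicates and 594 without replicate 3. Each population was represented by 1 such cross, so population and family cannot be separated. Crosses between populations were then placed on a scale between the within-population crosses of their parents, on gene models called between those at Pre and measured at Ambient and Hot, where 1 is the level of the first-named population's cross, -1 that of the second-named and 0 the middle. CUxSB lay at 0.791 ± 0.146 (SD, n = 2 treatments, 1832 gene models), near the CU end. CUxBK lay at 0.779 ± 0.409 (4210 gene models), from 0.490 in 1 treatment to 1.068 in the other. LSxCU lay at -0.244 ± 0.042 (1825 gene models), also on the CU side. DRxSB lay at 0.173 ± 0.058 (3037), SBxBK at -0.115 ± 0.107 (3119) and LSxSB at 0.108 (1085, Ambient alone, no SD). With gene models of at least 5 on the mean log2 CPM scale alone, SBxBK moved to -0.337 ± 0.032, LSxCU to -0.363 ± 0.084 and LSxSB to -0.0431, and the treatments of CUxBK lay at 0.232 and 1.356.

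In juveniles at Ambient, SED was set against C1, the comparison with the most calls. Amillepora09062-RA was near absent in SED, with 2 counts among 8554456 over 28 libraries, against 1448 among 12160863 over 29 C1 libraries (121.5 ± 41.2 CPM, SD). That is a 509-fold lower rate, with a 95% counting interval of 140.7 to 4209-fold. Amillepora04961-RA was 119.1-fold lower in SED, at 1.91 ± 3.43 against 243.4 ± 147.3 CPM (interval 75.2 to 201-fold). Amillepora07197-RA was 25.9-fold higher in SED, at 676.9 ± 559.2 against 26.6 ± 12.4 CPM, and Amillepora23389-RA was 17.1-fold higher, at 943.2 ± 249.1 against 58.1 ± 69.9 CPM. All 4 differed in the same direction in 10 of 10 crosses. In all, 1227 of 8954 gene models were higher in SED and 1455 lower (edgeR). Among them, 22 were more than 8-fold lower in SED and 5 higher by as much. The counting intervals cover counting error only. Column names carry a sequencing index number, and within a cross C1 libraries came first in it (14.6 ± 7.13 positions before the cross mean, n = 29) and SED last (15.4 ± 6.02 positions after, n = 28). With the index number as a covariate 770 models passed, and the 4 named ones stayed called at 93.2% to 117.1% of their log2 fold change. Within cross and treatment, 1 model followed the index number over all 117 early-block libraries, 354 did in C1 alone, 37 in SED alone and 0 in D1 or SS.

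**Figure D3:**
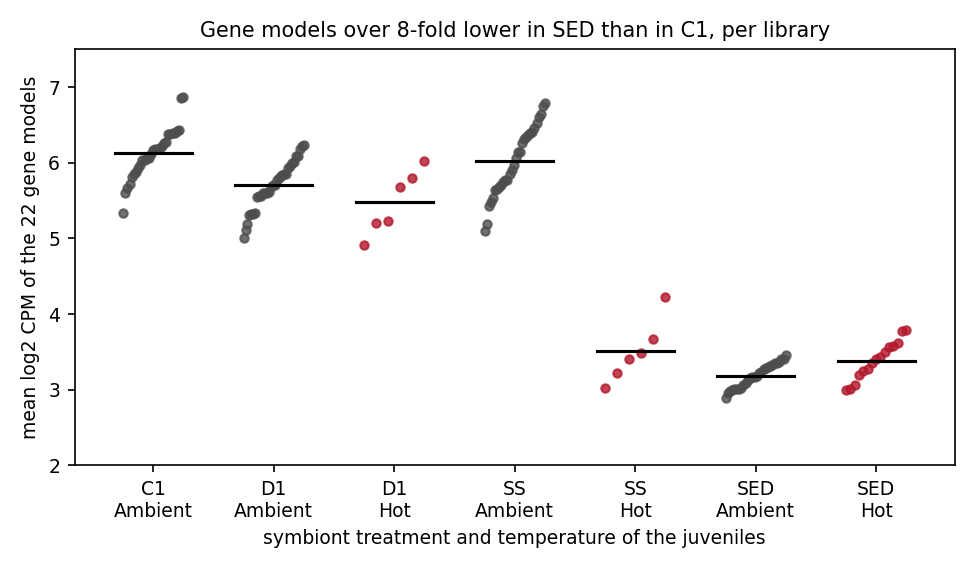
Mean log2 CPM of the 22 gene models more than 8-fold lower in SED than in C1 at Ambient, 1 point per juvenile library (Ambient grey, Hot red), with a bar at each group's mean. SED libraries lie near 3 at both temperatures, C1, D1 and SS Ambient libraries near 6, and SS Hot libraries from 3.02 to 4.22.

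SS juveniles differed from C1 partly in the same gene models. Amillepora07197-RA was 14.8-fold higher in SS, at 391.4 ± 184.5 CPM (SD, n = 30), and Amillepora23389-RA was 10.5-fold higher, at 589.3 ± 148.1 CPM. Amillepora12983-RA was 6.25-fold lower in SS, at 6.32 ± 4.36 against 42.6 ± 35.0 CPM, and Amillepora04321-RA, which also fell with heat in larvae, was 5.02-fold lower, at 114.7 ± 83.2 against 593.4 ± 250.2 CPM. Each of these held in 10 of 10 crosses. SS against C1 gave 418 higher and 381 lower gene models (edgeR). This contrast and SED against C1 share the C1 libraries. Of the 799 calls, 578 were also called in SED against C1, 558 of them in the same direction. Of those, 280 were down in both, against 61.9 for independent lists, and the rest up in both, against 57.3. These expected counts do not allow for the shared C1 libraries, which by themselves can add to the overlap. Across gene models the log2 fold changes of the 2 contrasts correlated at r = 0.578, against 0.4934 in simulations without any effect on the same controls and 0.442 with the C1 libraries split between the contrasts, and their covariance was 0.0583 against 0.0105 simulated. With the index covariate 511 models passed and the 4 named ones stayed called at 97.05% to 131.4% of their log2 fold change, and leaving out the libraries of 1 replicate number gave 32.04% to 164.7% of the 799.

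D1 and C1 juveniles differed in fewer models, with a few large differences. Amillepora32533-RA stood at 42.3 ± 22.2 CPM in D1 (SD, n = 32) and at 2.04 ± 2.39 CPM in C1, a 21.1-fold lower rate of counts (interval 14.0 to 33.3-fold). It was at 0.908 ± 1.80 CPM in SS, 1.59 ± 2.39 CPM in SED and 0.894 ± 1.28 CPM in Ambient larvae. Amillepora17006-RA had a 17.0-fold higher rate in D1 (interval 11.2 to 27.2-fold), at 37.5 ± 61.4 against 1.96 ± 3.32 CPM. Amillepora07069-RA had the opposite pattern, at 1.65 ± 2.45 CPM in D1 against 37.3 ± 20.1 CPM in C1, a 21.6-fold difference in rate (interval 13.7 to 36.2-fold), with 20.2 ± 14.9 CPM in SS, 1.99 ± 2.95 CPM in SED and 1.69 ± 1.48 CPM in Ambient larvae. Amillepora08383-RA was 4.0-fold lower in D1 (63.3 ± 93.4 against 229.4 ± 241.8 CPM, in 8 of 10 crosses), and the other 3 differed the same way in 10 of 10. Altogether 566 models differed (edgeR), 300 of them lower in D1 and the rest higher. Leaving out the libraries of 1 replicate number in turn gave from 27 to 1476 calls, and the index covariate gave 197, with the 4 named models still called at 74.59% to 124.1% of their log2 fold change.

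Several of these models also led the remaining contrasts. SS against D1 gave 136 higher and 91 lower models, led by Amillepora07069-RA (12.6-fold higher rate in SS, interval 7.89 to 21.3-fold) and Amillepora15375-RA (4.60-fold, 89.3 ± 60.8 against 18.9 ± 18.8 CPM), and by Amillepora32533-RA (43.9-fold lower rate in SS, interval 24.3 to 88.6-fold) and Amillepora17006-RA (6.99-fold lower). The SS mean of Amillepora17006-RA, 9.66 CPM, rests on 1 library at 248.3 CPM and is 1.43 ± 2.57 CPM without it (n = 29). In the index order SS and D1 libraries lay together (-1.73 ± 5.52 and 1.47 ± 6.78 positions from the cross mean), and the index covariate left 228 calls there. SED against D1 gave 468 higher and 668 lower models. Amillepora01102-RA was 7.49-fold higher in SED, at 1101 ± 371 against 153.3 ± 119.8 CPM, and Amillepora07197-RA 7.93-fold. Amillepora09062-RA had a 395-fold lower rate in SED (interval 109 to 3264-fold) and Amillepora04961-RA a 73.2-fold lower rate (interval 46.2 to 123.8-fold). SED against SS gave 628 higher and 917 lower models. Amillepora19310-RA was 5.34-fold higher in SED (18.0 ± 19.0 against 4.07 ± 6.65 CPM) and Amillepora24973-RA 4.66-fold (43.9 ± 32.4 against 8.97 ± 7.65 CPM), while Amillepora04293-RA had 2 counts in SED and 826 in SS, a 305-fold lower rate (interval 84.1 to 2521-fold). Over all 4 treatments 2727 of 8954 models differed (edgeR F-test). The index covariate gave 1293 for this test, 699 for SED against D1 and 768 for SED against SS, and the models named in these contrasts stayed called.

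Heat in juveniles was tested within the 14 combinations of cross and symbiont treatment that had both temperatures, with 27 Hot and 42 Ambient libraries. Amillepora13084-RA fell from 18.1 ± 29.6 CPM at Ambient to 0.483 ± 1.29 CPM at Hot (SD over libraries, and 0.299 ± 0.889 CPM at Hot without the highest library) and Amillepora07953-RA from 14.8 ± 12.8 to 1.57 ± 2.07 CPM, each in 13 of 14 combinations. Amillepora02878-RA rose from 25.1 ± 32.8 to 181.3 ± 329.3 CPM, 5.58-fold, in 13 of 14. Amillepora12232-RA rose from 2.05 ± 12.6 to 8.99 ± 14.6 CPM in 12 of 14, and stood at 4899 ± 1351 CPM in Ambient larvae. Its Ambient mean rests on 1 library at 81.89 CPM and is 0.10 ± 0.454 CPM without it (n = 41). Altogether 1600 of 9412 gene models were higher and 1622 lower at Hot (edgeR). Temperature was nearly confounded with the index numbers. Of the 27 Hot libraries, 23 were in a late block of index numbers that held 2 Ambient libraries, both D1. The other 4 were in the early block with all other Ambient libraries. These 4 Hot libraries held the last index numbers of the early block, after all of its Ambient libraries. The early block alone therefore cannot separate temperature from index order. With 1 mean per combination and block 0 models passed (1012 at an unadjusted p under 0.05), the early block alone gave 100 (66 higher, 34 lower), block as a term 50, and block as a term without the 2 late Ambient libraries 409. Late minus early libraries at equal temperature and combination also gave 0 (592 of 8917 at an unadjusted p under 0.05), and Hot libraries alone 0 (331 of 7979). With block as a term the log2 fold change of Amillepora12232-RA went from 2.87 to -0.00874 and DESeq2 gave it an adjusted p of 0.0524. Over the fits that take block into account the log2 fold change of Amillepora02878-RA stayed at 2.26 to 2.78 (2.48 before) with an adjusted p of 0.0388 to 0.226, and that of Amillepora13084-RA at -4.24 to -5.46 (-4.55 before) with an adjusted p of 0.0147 to 0.22. That of Amillepora07953-RA, -2.83 before, was -1.46 (adjusted p = 0.435) with block as a term and -3.10 (adjusted p = 0.059) also without the 2 late Ambient libraries.

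**Figure D4:**
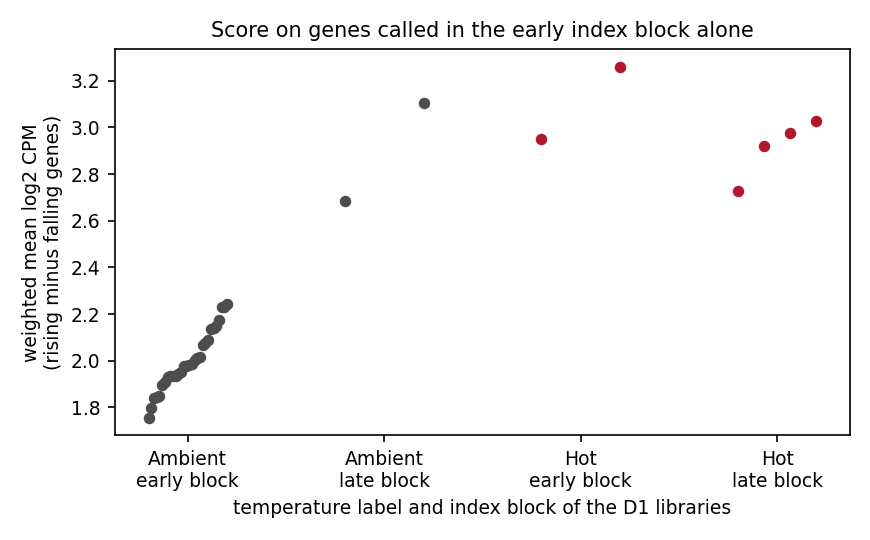
Score of each D1 juvenile library, by temperature label and index block, on the 100 gene models called between Hot and Ambient in the early block alone (weighted mean log2 CPM, rising minus falling models). Early-block Ambient libraries lie from 1.75 to 2.24, the 6 Hot libraries from 2.73 to 3.26, and the 2 late-block Ambient libraries at 2.68 and 3.1. The early-block libraries of SBxSB and LSxLS took part in choosing these models.

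The response to heat also differed between symbiont treatments for 131 of 9764 gene models (edgeR F-test of the difference among D1, SED and SS). The count was 30 without replicate 2, 55 without replicate 1 and 406 without the low-count filter. Hot libraries came from CUxDR, DRxSB, LSxLS and SBxSB in D1, from BKxBK, DRxSB and SBxSB in SS, and from 7 crosses in SED. The fit has 1 heat effect per treatment, so differences between crosses in their response can enter these counts. Hot minus Ambient called 466 models in D1 (6 Hot libraries), 2189 in SED (15) and 558 in SS (6). The 22 models that were low in SED at Ambient were compared between temperatures in SS and D1. In SS their mean log2 CPM was lower at Hot than at Ambient by a mean difference of -2.6 ± 0.389 (SD over 3 combinations; two-sided exact permutation p = 0.001 over 1000 arrangements within combination, the smallest they can give), and 19 of the 22 fell. In D1 the difference was -0.419 ± 0.413 (4 combinations; exact permutation p = 0.014) and 4 fell. SED is not tested on them, since its Ambient libraries were used to choose them. Amillepora09062-RA fell from 129.2 ± 61.4 CPM in SS Ambient (n = 30) to 2.32 ± 3.33 CPM in SS Hot (n = 6; 5 counts in all, and 1.08 ± 1.55 CPM without the highest library), while in D1 it was at 95.2 ± 32.2 CPM at Ambient and 65.9 ± 19.1 CPM at Hot, and the difference between the 2 effects passed (log2 difference -5.36, SE 0.52, adjusted p = 6.58e-10, edgeR). Of the 22 models 13 fell more in SS than in D1, and over all models the effect of heat differed between SS and D1 for 65, more negative in SS for 57 and more positive for 8. Within index blocks 3 models passed the test among the 3 treatments, and the early block alone gave 4, while block as a term gave 115.3% of the 131, and 175 models without the 2 late Ambient libraries.

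Larval and juvenile heat responses were compared over 9343 gene models tested in both stages, which share no libraries. Amillepora13087-RA, the second leading model in larvae, stood at 1828 ± 1583 CPM in D1 Ambient and 4232 ± 939 CPM in D1 Hot juveniles, at 1368 ± 713.9 and 2653 ± 1178 CPM in SED and at 1604 ± 1367 and 3240 ± 942 CPM in SS. Amillepora13086-RA stood at 35.9 ± 53.5 and 44.3 ± 63.2 CPM in D1, where the Hot mean rests on 1 library at 172.7 CPM and is 18.6 ± 6.47 CPM without it (n = 5), at 13.5 ± 17.9 and 37.1 ± 46.9 CPM in SED, and at 45.6 ± 103.8 (27.6 ± 34.2 without 1 library at 565.8) and 51.3 ± 45.2 CPM in SS. Amillepora04321-RA, which fell in larvae, stood at 384.2 ± 157.8 and 67.7 ± 17.3 CPM in D1, at 247.2 ± 193 and 231.6 ± 140.9 CPM in SED and at 114.7 ± 83.2 and 236.8 ± 74.7 CPM in SS, so only D1 showed a fall in its means like that of larvae. There were 759 models up in both stages against 413.6 for independent lists and 585 down in both against 328.3. Of models down in larvae, 140 were up in juveniles against 327.9 for independent lists. Of 1669 models called in both stages 1344 (80.5%) went the same way, and across gene models the log2 fold changes gave r = 0.275 and rho = 0.311. The limits from the index blocks apply to the juvenile side.

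In juveniles, 1173 of 8199 gene models differed among the 5 within-population crosses at Ambient, 2520 without the low-count filter and 465 without replicate 2. The reciprocal pair CUxDR and DRxCU, the same 2 populations with their order exchanged, differed in 1 of 7796 models (480 at an unadjusted p under 0.05) by edgeR and in 8 by DESeq2. Leaving out the only late-block library in this test gave 0, while without the low-count filter 96 models were higher and 55 lower, so the count depends on the filter. On the scale between parental crosses, juvenile DRxSB lay at -0.226 ± 0.067 (SD over 3 symbiont treatments, 26 gene models called at C1), and the other juvenile crosses had 0 to 9 such models, too few for a position.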

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

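The tests of the sequencing index block, the temperature labels, the algal reads, the SS Hot labels and the shared culture, and the count of SS against D1, were chosen after the results were seen.

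Among 16 sets of values searched for a member far from the others, 3 such values were found, and chance gives about 1 in 20 sets. In larvae, CUxBK stood apart from the other 9 crosses: its heat response correlated across gene models with theirs at r = 0.647 and 70.97% of models moved the same way, against 88.4% to 93.7% in the other crosses. In juveniles of DRxDR the slope of D1 minus C1 on the larval heat response was the highest, at 0.191, against a mean of -0.0311 ± 0.0883 (SD, n = 10 crosses). Differences between groups were found in the larval heat response among 10 crosses (3418 gene models), in the juvenile heat response among D1, SED and SS (131) and between SS and D1 (65).

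The first pattern is the low mean of the 22 models in SS juveniles at Hot, where 19 of the 22 were called as falling. It stood at 3.51 ± 0.416 on the log2 CPM scale (SD, n = 6), near SED Hot (3.38 ± 0.257, n = 15). Ambient larvae stood at 2.99 ± 0.212 (n = 33). Larval libraries were scaled apart and are deeper, so the prior count of 2 raises low values less there. Their mean is therefore not set against those of juveniles. D1 Hot was at 5.47 ± 0.423 (n = 6), after a smaller fall (-0.419 within combinations, exact permutation p = 0.014). A wrong label, SED libraries named SS, fits the calls. In the 2 crosses with Hot libraries of both, SS Hot and SED Hot (4 against 4) differed in 0 models by edgeR. The highest other split gave 2, of 18 splits with the real one included, and SS and SED Ambient libraries at that size differed in 43. However, 1 SED Hot library of each cross held far more Amillepora23389-RA (1439.6 and 1643.9 CPM) than any SS Hot library (at most 192.4) and the other did not (43.7 and 82.5). Unlike the 22 models, some named models went with the labels over all Hot libraries. Amillepora24973-RA stood at 50.2 ± 35.25 CPM in SED Hot and 15.1 ± 26.7 in SS Hot (8.97 ± 7.65 in SS Ambient). Amillepora01102-RA stood at 778.6 ± 410.2 and 306.1 ± 231.8 CPM (322.3 ± 158). Reads of algae counted on coral models cannot be told apart from coral genes that respond to algae, since 7 of the 22 models reached 10 CPM in Ambient larvae, between the bounds that would have decided it, and the word host in the juvenile column names does not say how reads were separated. A biological explanation, that SS juveniles lost their algae or the response to them under heat and D1 juveniles did not, may hold equally and was not tested, since algal cells were not measured here. SED standing apart at Ambient is not explained by its lower depth (1703 models after thinning, against 322 for D1 and 501 for SS) nor by a single cross (at least 2343 models without any 1 cross). Index order stays open, since within a cross C1 libraries came first and SED last. With the index number as a covariate SED against C1 called 770 models, against 2682 without it. SS against C1 then called 511 of 799 and D1 against C1 197 of 566. Index order and treatment nearly coincide in SED against C1, so the covariate costs calls there even without an index effect. SS against D1, whose libraries lie together in the order, called 228 models with it and 227 without. The 4 models named for SED against C1 stayed called.

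The second pattern is the juvenile heat response, which nearly coincides with the late index block. The block as its whole cause is argued against by the 4 early-block Hot libraries: on 2365 models called in the other combinations they moved the same way with slopes of 0.752, 0.416, 0.502 and 0.542 (median 0.522), where a pure block effect gives 0, and depth by 1968 calls after thinning to equal totals. A wrong temperature label on the 2 late-block Ambient D1 libraries could account for part of the loss of calls (50 with block as a term, 409 without these 2, 100 in the early block, which lacks them, against 3222) and cannot be told apart from a real block effect: they scored 2.684 and 3.1 on the early-block heat models, above all 30 early-block Ambient libraries (at most 2.24) and near the 6 Hot ones (2.73 to 3.26), and on 4349 larval heat models 1.0 and 1.507, where the Ambient (0.783 to 1.35) and Hot (1.106 to 1.362) ranges overlap, so that this score decides little. The early-block D1 libraries of SBxSB and LSxLS took part in choosing the early-block heat models, so their separation is by choice. The 4 late-block Hot D1 libraries took no part and scored 2.727 to 3.029. CUxDR and DRxSB each held 4 D1 Ambient libraries and 1 D1 Hot library, and every other juvenile group held 2 or 3. These sizes go with a wrong label but do not settle it. Late and early Hot libraries, without the late-block Ambient ones, differed in 0 models (331 of 7979 at an unadjusted p under 0.05). With 4 early libraries that does not exclude a block effect. The 4 early-block Hot libraries came after all Ambient libraries of their block in the index order. Their slopes and the 100 early-block calls therefore do not separate temperature from index order. How much of the 3222 calls is temperature and how much is block or index order stays open, as does heat itself as the biological explanation.

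The third pattern is the difference between larval crosses in response to heat. Depth stays open, since the slopes fell with depth (Spearman's rho = -0.709, permutation p = 0.0266), although this rests on 2 crosses and 2492 models were still called after thinning to equal totals. The depths themselves differed little, with means per cross from 802100 (DRxDR) to 892500 counts (CUxBK). A shared culture stays open by design, because each cross and treatment has 1 title number, and the cross and its culture cannot be told apart. A biological difference between crosses may hold too and was not tested apart from these.

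Other splits of the same libraries, 40 per result with the real one included, argued against chance for most results. In all but the reciprocal crosses only the real split gave as many calls, 1 of 40, the smallest share they can give. For larval cross by temperature and juvenile heat by symbiont the temperature labels were shuffled within cross or combination. That removes the whole heat effect and not only its difference between groups, so these splits cannot decide whether chance gave those counts. The real count and the highest of the other splits were 5915 and 3799 for larval heat, 1499 and 14 for larval time, 5714 and 3725 for Hot against Pre, 1070 and 100 for larval population, and 3418 and 758 for larval cross by temperature. The median of the other splits was 0 in each. In juveniles they were 2727 and 3 for symbiont, 566 and 1 for D1 against C1, 799 and 8 for SS against C1, 2682 and 1 for SED against C1, 227 and 5 for SS against D1, 1136 and 1 for SED against D1, 1545 and 12 for SED against SS, 3222 and 1 for heat, 131 and 2 for heat by symbiont, and 1173 and 3 for population. For the reciprocal crosses chance was not excluded: 5 of 40 splits called at least the 1 real model, and the highest called 28.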

How the results depend on the processing

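Among alternative counts of called models, 205 were within 1.5 times the reported count and 59 beyond, and of 708 alternative values of named models 698 kept direction and call, 8 lost the call and 2 turned. The index block and index number alternatives were chosen after seeing the data. Larval heat, Hot against Pre and the overlap between stages stayed within 1.5 times in all alternatives run (4936 to 6846, 4805 to 6618 and 1423 to 1725). The cause of the shifts was not tested, except that leaving out libraries leaves fewer samples. Thinning D1 against C1 to 158481 counts per library left 322 of 566 calls. The planned removal of libraries under 100000 counts gave no value in juveniles, whose smallest library held 158481.

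With libraries as replicates, larval heat gave 6797, larval time 3680 (50.9% higher, against 28.3% of calls on summed profiles), Hot against Pre 6532 and larval population 4991. Same-numbered libraries did not deviate together (mean r = 0.000372 against -0.00018 for other numbers), so the numbers pair nothing; a replicate block added to these fits gave 6846, 3685, 6618 and 5012, and 3358 for larval cross by temperature, so the block moved little. Without the low-count filter, larval population gave 1787, juvenile heat by symbiont 406, juvenile population 2520 and the reciprocal crosses 1.5e+02 (rounded, 96 higher and 55 lower), and the higher share of calls fell from 47% to 35.1% in D1 against C1 and from 52.3% to 41.8% in SS against C1. DESeq2 gave 8 for the reciprocal crosses.

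The index number as a covariate gave 1293 for symbiont, 197 for D1 against C1, 511 for SS against C1, 770 for SED against C1, 699 for SED against D1 and 768 for SED against SS. Juvenile heat gave 0 within blocks (1012 at an unadjusted p under 0.05, edgeR), 50 with block as a term, 100 in the early block and 409 with block as a term and without the 2 late Ambient libraries. Amillepora12232-RA turned to -0.00874 and -2.39 in the second and the last of these. Heat by symbiont gave 3 within blocks and 4 in the early block, but 175 with block as a term and without the 2 late Ambient libraries, and the reciprocal crosses 0 without the 1 of these libraries they hold.

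Leaving out each replicate number, cross or combination in turn gave ranges of 931 to 1666 (larval time), 594 to 1066 (larval population), 2017 to 2056 (larval cross by temperature, 2 libraries per group), 1517 to 3002 (symbiont), 27 to 1476 (D1 against C1), 2.6e+02 (rounded, 32.04% of 799) to 1316 (SS against C1), 1541 to 2752 (SED against C1), 70 to 240 (SS against D1), 717 to 1129 (SED against D1), 754 to 1465 (SED against SS), 1550 to 3319 (juvenile heat), 30 to 135 (heat by symbiont), 465 to 683 (juvenile population) and 0 to 2 (reciprocal crosses). On the parental scale, models of at least 5 in log2 CPM gave -0.3626 for LSxCU, -0.3373 for SBxBK and -0.04306 for LSxSB, which turned, and a selection at 0.01 gave 0.05918 for LSxSB. The rho of the Pre level and the fall of heat-reduced models turned to 0.1394 with the top 100 models.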

Other observations

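The tests of heat effects of single models and of larval transcripts in juvenile libraries were chosen after the results were seen; those of the other hypotheses were set before the data were examined.

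Some named models changed with heat differently in SS and D1 juveniles. In the combinations with both temperatures Amillepora23389-RA stood at 66.9 ± 65.3 CPM in SS Hot (SD, n = 6; 41.8 ± 24.7 without the highest library) against 590.8 ± 88.5 in SS Ambient (n = 9), and in D1 at 1106 ± 236.1 CPM in Hot (n = 6) against 403.2 ± 441.8 in Ambient (n = 14), and the difference between the 2 effects passed (log2 difference -4.77, SE 0.82, adjusted p = 9.58e-05, edgeR). Amillepora07197-RA followed, at 14.7 ± 7.84 CPM in SS Hot and 563.3 ± 216.2 CPM in D1 Hot against 437.3 ± 259.3 and 116.2 ± 175.3 CPM at Ambient (73.6 ± 75.9 in D1 without the highest library; log2 difference -7.60, SE 1.19, adjusted p = 2.13e-05). SED Hot held 727.8 ± 561.5 CPM of Amillepora23389-RA (n = 15, 43.7 to 1644) and 94.3 ± 96.5 CPM of Amillepora07197-RA (7.502 to 322.8), with means above those of SS Hot, and the effects of heat in SS and SED did not differ at the threshold (adjusted p = 0.0594 and 0.681). Amillepora04293-RA had 0 CPM in all 15 SED Hot and all 6 SS Hot libraries and 29.9 ± 24.5 CPM in D1 Hot, against 50.9 ± 28.7 CPM in SS Ambient and 19.4 ± 16.9 CPM in D1 Ambient (log2 difference of SS and D1 -7.64, SE 1.19, adjusted p = 0.000137). Other named models differed the other way: Amillepora04321-RA (log2 difference 3.23, SE 0.72, adjusted p = 0.00848) fell in D1, from 338.8 ± 155.5 to 67.7 ± 17.3 CPM, and not in SS. Amillepora17006-RA (4.89, adjusted p = 0.0407) and Amillepora32533-RA (5.05, adjusted p = 0.0407) also passed, the first with 1 SS Hot library at 137.8 CPM that raises the SS Hot mean from 7.68 to 29.4 CPM and the other with 0 CPM in all 9 SS Ambient libraries. Most Hot libraries are in the late index block, so these effects carry its limits. SS and D1 Hot libraries came partly from different crosses, so differences between crosses can enter too.

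Amillepora12232-RA, which rose in juvenile Hot, was among 5 models abundant in larvae (at least 300 CPM) with a median of 0 and a 90th percentile under 5 CPM in early-block Ambient juveniles. Summed over these 5, juvenile libraries held a median of 0.154% of the larval level in the late-block Hot libraries (n = 23, 0 to 1.01%), 0.0808% in late-block Ambient (n = 2) and 0.0352% in early-block Hot libraries (n = 4, 0.0242 to 0.152%). The median of 0.0257% in early-block Ambient libraries (n = 117) is low by the choice of the 5, and a single library there, D1 LSxLS replicate 1, reached 4.27%. A hypothesis is that larval RNA in late-block libraries accounts for the models that rose at Hot. At the mean share of 0.265% it would reach 0.5 of the rise for 1 of the 1600 models that rose, so it could account for that model alone. Whether the share comes from larvae among the juveniles or from other libraries was not tested.

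SED juveniles might resemble heated animals. On models called in larval heat, the slope of SED minus C1 on the larval response was -0.0753 ± 0.0733 (SD, n = 10 crosses). It lay at or below 0 in 9 of 10 crosses, against SED being more heat-like than C1. The slope was -0.055 ± 0.101 for SS minus C1 and -0.0311 ± 0.0883 for D1 minus C1, above 0 in 3 and 2 crosses. All 3 contrasts share the C1 libraries, so the sign is not particular to SED and may come from C1. Of 1354 models called in both contrasts 36.3% went the same way.

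Heat might move larvae further along the change from Pre to Ambient. With each effect taken from other crosses than the other, the slope of Hot minus Ambient on Ambient minus Pre was -0.0595 in 1 set of crosses and -0.0747 in the other, where faster development needs a slope above 0.

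Front-loading, a higher level of heat-induced models before exposure in crosses that respond less, may hold: rho was -0.564 over 10 crosses with a permutation p of 0.09455. This p was set beforehand to argue against it, but with 10 crosses a p over the threshold excludes nothing, so the hypothesis stays open.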
